A study of Danio rerio with 6 samples.

How the data were processed

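Kidney marrow, the blood-forming tissue of adult zebrafish, was taken from fish aged 3 to 5 months, and vigorous pipetting and a 70 micron filter turned it into a cell suspension before total RNA was sequenced, per the labels' protocols. Kidney tubules surround the marrow in this organ, and the labels name no sort of the suspension. The 6 libraries fall into 2 genotypes, wild type and tet2 -/- (called tet2 mutant here), with 3 biological replicates each. The labels describe neither the mutant allele, the sex of the fish, nor how many fish made a library.

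The values deposited by the authors are raw read counts per Ensembl gene, 1 table per library with 31484 genes. Reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to the genome build GRCz10, per the submitters' processing notes. The counting tool, the strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Reads from overlapping genes, and from near-identical gene copies, are therefore of uncertain origin. All coordinates are those of the count tables on GRCz10, for whole genes. Symbols came from a name table that matched 25752 of the 31484 gene IDs (81.8%). They are printed as that table gives them, many in the capitals used for human genes, and 1632 symbols stand on more than 1 gene ID. Synonyms from a RefSeq gene table (assembly GRCz12tu) were used only to match listed names.

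Total counts ran from 41285460 to 49229143 per library. A floor of 3 counts equals between 0.0609 and 0.0727 CPM, the unit of counts scaled to the library total, and floors cover counting error only. No 2 libraries of a genotype were copies of each other, since the chi-square per degree of freedom of their counts lay between 56.4 and 167. A check of GC content was not run, because no GRCz10 sequence was used here.

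Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by genotype, libraries were scaled by TMM factors, and a quasi-likelihood F test (two-sided) compared the genotypes with no other covariate. This left 21893 genes tested and 9591 untested for low counts. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by TMM, log2 fold changes are mutant minus wild type, and standard errors (SE) were derived from the fold change and its F statistic. Folds are fitted log2 fold changes on the linear scale, except where counts are given. Means are given with the standard deviation (SD) over n = 3 libraries.

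Gene lists of 27 kinds were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives other than those said to be chosen later. They comprise 8 blood cell types, 7 other cell types that the suspension could hold, and 12 pathways. Of the 564 listed symbols, 528 matched a gene. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Beside it stand camera with an estimated correlation and fry, whose directional p asks whether a list's genes move one way on balance and whose mixed p asks whether they change in either direction. Passing members were counted over all genes tested and adjusted over the list alone.

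The rule for named genes took TET2, TET1, tet3 and TDP1 always. It took up to 12 rises and 12 falls among passing genes, ranked by size, that had at least 5 CPM in the higher genotype, no overlap between genotypes and a descriptive symbol; 7 rises and 14 falls were eligible. It added the 5 genes with the smallest p, and for each list up to 4 passing members, or the 2 members with the smallest p where none passed. Gene families, second marker sets and single genes outside this rule are described as chosen after the values were seen. The share of counts in 14 haemoglobin genes was compared with an exact two-sided permutation test, whose smallest possible p is 0.1 with 3 libraries against 3. Changed genes within 10 Mb of TET2 were compared with those elsewhere by Fisher's exact test.

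The labels number the replicates 1 to 3 in each genotype without saying what the numbers share. Deviations of log2 CPM from the genotype mean were therefore correlated across 13294 genes, which are not independent replicates. Same-numbered libraries had r = 0.380, 0.559 and 0.694 for numbers 1, 2 and 3, and differently numbered ones had r between -0.546 and 0.283. The pairing was thus read from the data, not from the labels, and is uncertain. Deviations from a mean of 3 libraries sum to 0, which forces part of the negative r. The libraries numbered 3 held the most egg transcripts of their genotype (zona pellucida CPM of 1105 and 4491). Egg content could by itself raise their r, which was not tested. A fit with the replicate number as a block was among the alternatives, and its values stand beside a result where it changes a call or moves a count by over 1.5 times.

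The test was checked on simulated counts for 21144 genes drawn from the libraries' fitted means and sizes with the replicate number kept. Of these, 200 genes with a mean of at least 1 CPM were changed, so recovery below 1 CPM was not checked. Calls among a further 30 genes, shifted 1.5-fold, were not counted as false. Without the block the test recovered 1.49% of genes changed 2-fold, 56.7% of those changed 4-fold and 81.8% of those changed 8-fold, and 0 of 93 calls were false. With the block it recovered 53.7%, 92.5% and 100% of these, and 30 of 195 calls were false (15.4%). That share is above the one the adjusted p threshold is meant to allow. Calls made with the block alone are therefore less certain than their adjusted p states. The p from camera was 1.07e-18 for a simulated list of 30 genes shifted 1.5-fold and 0.462 for an unshifted one. Genes were drawn independently, so these p values do not check the preset correlation of 0.01. The real lists that passed had estimated correlations from 0.18 (muscle) to 0.71 (germ cell). The simulated means came from a fit with the block, so its better recovery holds only if the numbers pair the libraries.

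The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, library totals alone, removal of haemoglobin genes, no filter on low counts, a filter of at least 1 CPM in 3 libraries, robust dispersion, the replicate block, and each library left out in turn. For the haemoglobin share they were alpha and beta globins apart, and for the region around TET2 windows of 5 and 20 Mb and the whole chromosome. An alternative chosen after seeing the data used the log2 zona pellucida CPM of each library as a covariate (the egg covariate), and another left out wild type 3 and tet2 mutant 3 together.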

Results

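Gene expression in kidney marrow was compared between 3 wild type and 3 tet2 mutant libraries of adult zebrafish, to ask which transcripts differ with the genotype. Tet2 belongs to the enzymes that oxidise 5-methylcytosine in DNA, and its loss is a known event in human blood disorders. The wild type libraries 1, 2 and 3 held 47228518, 41285460 and 43220770 counts, and the tet2 mutant libraries held 49229143, 46637322 and 48300262. All values below are CPM with SD over n = 3 libraries per genotype, unless single libraries are named.

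The targeted gene, TET2 (ENSDARG00000076928, chromosome 1, 25662646 to 25693594), was transcribed in all 6 libraries. Its values were 48.1, 52.5 and 48.1 CPM in the wild type libraries and 51.1, 45.1 and 30.4 CPM in the mutant ones. The log2 fold change was -0.23 (SE 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.696), and it was -0.06 without tet2 mutant 3 and -0.39 without tet2 mutant 1. Since the allele is not described and need not lower the transcript, this level does not check the labels. TET1 (ENSDARG00000075230), of the same enzyme family, had 18.5 ± 2.16 CPM in wild type and 20.6 ± 5.02 in mutants, and tet3 (ENSDARG00000062646) had 57.4 ± 2.81 and 54.8 ± 12. TDP1 (ENSDARG00000073866), which removes topoisomerase I remnants from DNA ends, had 10.8 ± 3.95 and 6.77 ± 0.615 CPM, with a log2 fold change of -0.67 (SE 0.28; edgeR, Benjamini-Hochberg adjusted p = 0.427).

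In the mutant marrow, areg, which encodes the epidermal growth factor receptor ligand amphiregulin, rose 9.37-fold from 7.48 ± 2.59 to 70.05 ± 26.4 CPM, and the cell adhesion gene chl1a rose 17.0-fold from 0.912 ± 0.151 to 15.6 ± 3.51. The lactate transporter gene SLC5A12 fell 2.91-fold and the amino acid transport partner gene cltrn 2.77-fold. The class I histocompatibility gene mhc1uba fell 4.18-fold, from 16.6 ± 2.91 to 3.96 ± 0.937 CPM, as the only 1 of 16 class I genes tested to pass. As a group, 14 of 18 skeletal muscle transcripts were lower when adjusted over the list alone, though 0 passed over all genes. The muscle list did not pass with an estimated correlation (camera of limma, Benjamini-Hochberg adjusted p = 0.323). Across the genome 66 of 21893 genes changed by edgeR's quasi-likelihood test, 21 higher and 45 lower in mutants, 65 of them at least 2-fold. An unadjusted p under 0.05 was reached by 2612 genes, against 1094.65 expected if p were uniform. The other splits of the 6 libraries into 3 and 3 gave from 204 to 2915 such genes. The highest was wild type 1 with tet2 mutant 1 and 2 against the rest. The excess is therefore not particular to the genotype.

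Among the named rises, chl1a (ENSDARG00000077881, chromosome 23, 11412343 to 11513888) had a log2 fold change of 4.09 (SE 0.27), and areg (ENSDARG00000076853, chromosome 5, 6192899 to 6228292) one of 3.23 (SE 0.36). The complexin gene cplx2a (ENSDARG00000018997, chromosome 1, 11576180 to 11591781), whose product binds the machinery of vesicle release, rose from 1.65 ± 0.804 to 13 ± 0.803 CPM (2.98, SE 0.38). A member of the deltex ubiquitin ligase family, dtx3lb.3 (ENSDARG00000104649, chromosome 11, 1581760 to 1591299), rose from 2.61 ± 0.371 to 11.2 ± 2.19 CPM (2.097, SE 0.24). The F-box gene fbxo44.9 (ENSDARG00000071029, chromosome 23, 17002163 to 17019098) rose from 1.23 ± 0.186 to 5.14 ± 0.57 CPM (2.06, SE 0.25). The chaperone gene hsc70 (ENSDARG00000012381, chromosome 15, 37934331 to 37949384) rose from 15.5 ± 1.91 to 56.4 ± 5.73 CPM (1.86, SE 0.14). A long noncoding RNA, linc-iglc3 (ENSDARG00000069839, chromosome 3, 58595291 to 58620762), rose from 21.1 ± 0.211 to 42.6 ± 1.6 CPM (1.02, SE 0.10); it overlaps 4 other genes, so its reads are of uncertain origin. Adjusted p for these 7 genes ran from 0.016 to 0.0461 (edgeR, Benjamini-Hochberg), and all 3 mutant libraries lay above all 3 wild type libraries for each.

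Among the named falls, RFESD (ENSDARG00000058725, chromosome 21, 11737208 to 11741824), which carries an iron-sulphur domain, fell from 12.6 ± 5.19 to 0.191 ± 0.112 CPM (log2 fold change -6.02, SE 0.60). The gene bif1.2 (ENSDARG00000101790, chromosome 21, 2243522 to 2247420) fell from 8.19 ± 1.77 to 0.25 ± 0.0758 CPM (-5.02, SE 0.35). The acyl-CoA binding gene acbd4 (ENSDARG00000027070, chromosome 12, 15526454 to 15577783) fell from 22.4 ± 5.31 to 1.69 ± 0.262 CPM (-3.73, SE 0.25). The otoancorin gene otoa (ENSDARG00000080675, chromosome 16, 22133134 to 22202744) fell from 7.77 ± 3.75 to 0.659 ± 0.119 CPM (-3.55, SE 0.45), and znf687a overlaps it on the opposite strand. The serine protease gene PRSS12 (ENSDARG00000061830, chromosome 1, 19376401 to 19449424) fell from 6.37 ± 2.11 to 0.547 ± 0.197 CPM (-3.53, SE 0.42). A HERC family ubiquitin ligase gene, herc56.1 (ENSDARG00000075785, chromosome 1, 49970042 to 49994129), fell from 6.42 ± 0.835 to 0.709 ± 0.112 CPM (-3.17, SE 0.26).

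The mitochondrial translation activator gene taco1 (ENSDARG00000062943, chromosome 12, 9267989 to 9277959) fell from 10.3 ± 2.15 to 1.83 ± 0.117 CPM (-2.49, SE 0.23). For mhc1uba (ENSDARG00000075963, chromosome 19, 7153929 to 7182175) the log2 fold change was -2.06 (SE 0.25). The alpha-glucosidase gene GANC (ENSDARG00000074556, chromosome 17, 45145494 to 45189197) fell from 20.7 ± 2.31 to 5.99 ± 0.523 CPM (-1.79, SE 0.16), with 1 gene overlapping it on the opposite strand. SLC5A12 (ENSDARG00000005004, chromosome 25, 34970048 to 35019227) fell from 45.3 ± 6.64 to 15.6 ± 2.55 CPM (-1.54, SE 0.17), and FIBIN overlaps it on the opposite strand. The collectrin gene cltrn (ENSDARG00000041644, chromosome 23, 40979784 to 41002264) fell from 62.3 ± 11.9 to 22.5 ± 2.5 CPM (-1.47, SE 0.17). DDC (ENSDARG00000016494, chromosome 16, 8384813 to 8429020), the aromatic amino acid decarboxylase that is also active in proximal tubule, fell from 103 ± 3.56 to 43.5 ± 4.79 CPM (-1.24, SE 0.12). Adjusted p for these 12 falls ran from 0.016 to 0.0463 (edgeR, Benjamini-Hochberg), with no overlap between the genotypes for any.

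**Figure D1:**
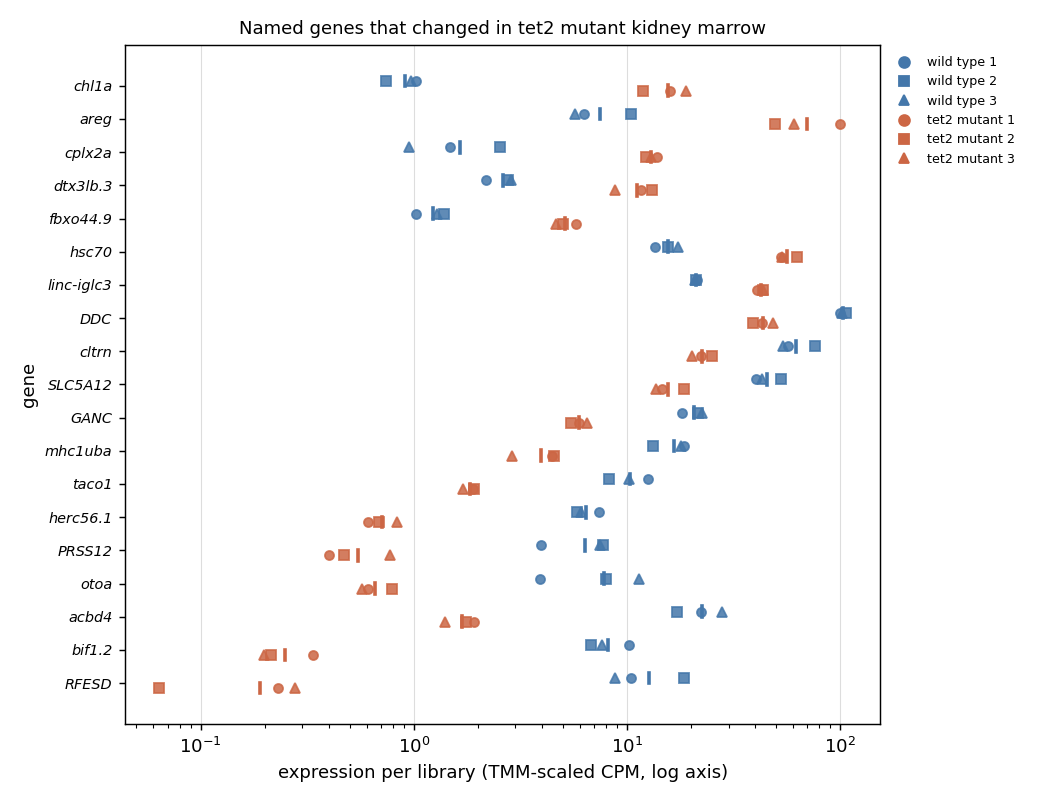
Expression of the named rises and falls in TMM-scaled CPM on a log axis, with 1 point per library (colour for the genotype, shape for the replicate number) and a vertical bar at each genotype's mean. For each gene drawn, the 3 mutant libraries lie on 1 side of the 3 wild type libraries.

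The smallest p belonged to a gene with only a clone-based name, si:dkey-18p12.4 (ENSDARG00000079703, chromosome 9, 30577170 to 30581999). It had 42.3 ± 8.1 CPM in wild type and 0.028 ± 0.033 in mutants, or 5545 against 4 counts, a ratio of 1531 with a 95% counting interval of 597 to 5619 (edgeR, Benjamini-Hochberg adjusted p = 0.0153). Another, si:dkey-27k4.4 (ENSDARG00000105651, chromosome 7, 37765583 to 37767788), rose from 2.53 ± 0.0657 to 12.2 ± 0.199 CPM (log2 fold change 2.27, SE 0.17). Such names, or none, belong to 36 of the 66 changed genes. In 23 of the 66 (34.8%) the mean was under 0.1 CPM in 1 genotype, 9 times in wild type and 14 times in mutants. With 0 counts in all wild type libraries, si:ch211-190k17.17 was at least 67.6-fold higher in mutants, and with 0 counts in all mutant libraries, ENSDARG00000100332 was at least 48.2-fold lower, each against 3 counts over the group; both were chosen after their values were seen. All 66 changed genes lacked overlap between genotypes, as did 3986 of the 21893 tested (18.2%), where chance gives 10%.

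The number of changed genes depended on every library. It was 6 without wild type 1, 3 without wild type 2, 15 without wild type 3, 2 without tet2 mutant 1, 2 without tet2 mutant 2 and 11 without tet2 mutant 3, while all 21 named passing genes kept their direction in each case. Only si:dkey-18p12.4 passed in all 6; chl1a and acbd4 passed in 3, bif1.2 in 2, hsc70, herc56.1 and si:dkey-27k4.4 in 1, and the other 14 in 0. With the replicate number as a block, 468 genes changed (257 higher, 211 lower, all 66 included), and DESeq2 called 999 (404 higher, 595 lower). In simulated counts 15.4% of calls with the block were false, more than the adjusted p threshold is meant to allow. Calls made with the block alone, here and below, are subject to that limit. Without wild type 3 and tet2 mutant 3, a choice made after seeing the data, 312 genes changed (249 higher, 63 lower) but areg, fbxo44.9, otoa and SLC5A12 missed the threshold. That comparison is confounded with egg transcripts, since zona pellucida CPM in the libraries left was 8.004 and 8.62 in wild type 1 and 2 against 679 and 442 in tet2 mutant 1 and 2 (1105 and 4491 in the libraries left out).

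Of the 28 kidney tubule transcripts measured, 22 had a log2 fold change below 0 (median -0.77). SLC5A12 passed over all genes, and 11 were lower when adjusted over the list alone. They include the endocytic receptors CUBN (76.4 ± 20.3 and 35.4 ± 6.25 CPM) and LRP2 (85.9 ± 25.4 and 37.3 ± 8.25, ENSDARG00000102506), the cation transporter SLC22A2 (72.9 ± 19.4 and 32.3 ± 4.85) and the cadherin CDH17 (231 ± 41.6 and 134 ± 23.6). The list fell relative to other genes (camera of limma, Benjamini-Hochberg adjusted p = 8.88e-07), with adjusted p = 0.877 with an estimated correlation. Its median was -0.49 without wild type 2. With the replicate block, 9 members passed over all genes, all lower, CUBN, LRP2, SLC22A2 and CDH17 among them, and 15 were lower when adjusted over the list alone. Multiciliated cell transcripts, from cells that line the tubules, had 11 of 15 members below 0 (median -0.34; camera of limma, Benjamini-Hochberg adjusted p = 0.156). Examples are foxj1b, with 3.28 ± 0.593 and 2.22 ± 0.932 CPM, and dnaaf19, with 5.16 ± 1.39 and 3.47 ± 2.21. Multiciliated cell transcripts passed without tet2 mutant 2, at a median of -0.67 (camera of limma, Benjamini-Hochberg adjusted p = 0.00299), and with the egg covariate, chosen after seeing the data, at -0.37 (adjusted p = 0.0335, camera of limma with Benjamini-Hochberg adjustment). In both of these fits 0 lists passed with an estimated correlation.

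Skeletal muscle transcripts, from a tissue that lies beside the kidney, had all 18 measured members below 0 (median -1.66). By edgeR 0 passed over all genes, 14 had an unadjusted p under 0.05, DESeq2 called 13 and voom 1, and 14 were lower when adjusted over the list alone. The troponin gene TNNI2 (ENSDARG00000013752) had 7.87 ± 1.22 CPM in wild type and 1.53 ± 0.474 in mutants, the tropomyosin gene tpma 26.8 ± 4.03 and 6.55 ± 2.85, and the actin gene actc1b 82.5 ± 15 and 26.2 ± 10.4. The list fell (camera of limma, Benjamini-Hochberg adjusted p = 1.16e-14), with adjusted p = 0.323 with an estimated correlation. With the replicate block, 4 members passed over all genes and 15 when adjusted over the list alone, all lower. They were TNNI2 (log2 fold change -2.39; edgeR, Benjamini-Hochberg adjusted p = 0.0324), tpma (-2.11, adjusted p = 0.0482), myhz2 and pvalb1.

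Endothelial and stromal transcripts were lower as lists. Of 19 endothelial transcripts, 18 were below 0 (median -0.37; camera of limma, Benjamini-Hochberg adjusted p = 0.00055, and adjusted p = 0.877 with an estimated correlation). The vessel gene clec14a had 22.4 ± 1.82 and 14.4 ± 2.02 CPM, and the junction gene ESAM 5.42 ± 1.04 and 2.85 ± 0.482. The endothelial median was -0.60 without wild type 1 and -0.68 without tet2 mutant 2, and the list still passed by camera with the preset correlation. Of 18 stromal transcripts, 14 were below 0 (median -0.30; camera of limma, Benjamini-Hochberg adjusted p = 0.0091, and adjusted p = 0.893 with an estimated correlation). The matrix gene POSTN has 2 copies, with 5.41 ± 1.29 and 2.48 ± 0.427 CPM for ENSDARG00000043806 and 6.95 ± 1.44 and 3.83 ± 0.747 for ENSDARG00000104267. The stromal call ended without tet2 mutant 1 (median -0.16, adjusted p = 0.0775 by camera of limma with Benjamini-Hochberg adjustment) and held without tet2 mutant 3 (-0.48). By edgeR 0 members of either list passed over all genes or adjusted over the list alone, 7 endothelial and 5 stromal members had an unadjusted p under 0.05, DESeq2 called 2 of each and voom 0. Adjusted over the list alone, 4 endothelial and 3 stromal members were lower with the replicate block.

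Egg and liver transcripts differed widely between libraries of the same genotype. Zona pellucida transcripts summed to 8.004, 8.62 and 1105 CPM in wild type 1, 2 and 3 and to 679, 442 and 4491 CPM in the mutant libraries. Outside the fixed tests, the first principal component of log2 CPM, the axis of greatest variation, held 64.1% of the variance over 13294 genes. All 11 zona pellucida genes among these stood in the top 500 by its loading. On this axis wild type 3 (23.8) lay with the mutant libraries (20.1, 8.30 and 67.1), apart from wild type 1 and 2 (-58.2 and -61.1). In the germ cell list 15 of 17 members were above 0 (median 1.71; camera of limma, Benjamini-Hochberg adjusted p = 0.0143, and adjusted p = 0.893 with an estimated correlation). The germ granule gene tdrd5 had 1.38 ± 2.03 and 6.25 ± 7.7 CPM, and the meiotic recombinase gene DMC1 0.928 ± 0.498 and 0.491 ± 0.306. By edgeR 0 members passed over all genes, adjusted over the list alone, or at an unadjusted p under 0.05, and DESeq2 and voom called 0. With the replicate block TDRD1 and tdrd5 were higher over all genes (tdrd5 log2 fold change 2.60; edgeR, Benjamini-Hochberg adjusted p = 0.0326) and 11 when adjusted over the list alone; with the egg covariate, chosen after seeing the data, the log2 fold change of tdrd5 was -0.31. The germ cell call ended without wild type 1 (median 1.25), wild type 2 (1.21) and tet2 mutant 3 (0.00), held without wild type 3 (4.86), and turned with that covariate (median -0.63; camera of limma, Benjamini-Hochberg adjusted p = 0.00318, and adjusted p = 0.774 with an estimated correlation). Liver transcripts had 13 of 17 members above 0 (median 0.97; camera of limma, Benjamini-Hochberg adjusted p = 0.745) but were highest in tet2 mutant 2, at 167 CPM for the fatty acid carrier fabp10a and 349 CPM for the transferrin tfa. Without that library the liver median was -1.84 (camera of limma, Benjamini-Hochberg adjusted p = 0.0429), and without tet2 mutant 1 it was 1.56 (adjusted p = 0.0375, camera of limma with Benjamini-Hochberg adjustment). It was 1.46 without wild type 3 and tet2 mutant 3 (camera of limma, Benjamini-Hochberg adjusted p = 0.034), and in these 3 fits 0 lists passed with an estimated correlation. The fabp10a means were 16.5 ± 12.7 and 60.4 ± 92.8 CPM, and those of tfa 32.3 ± 32.8 and 125 ± 195.

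**Figure D2:**
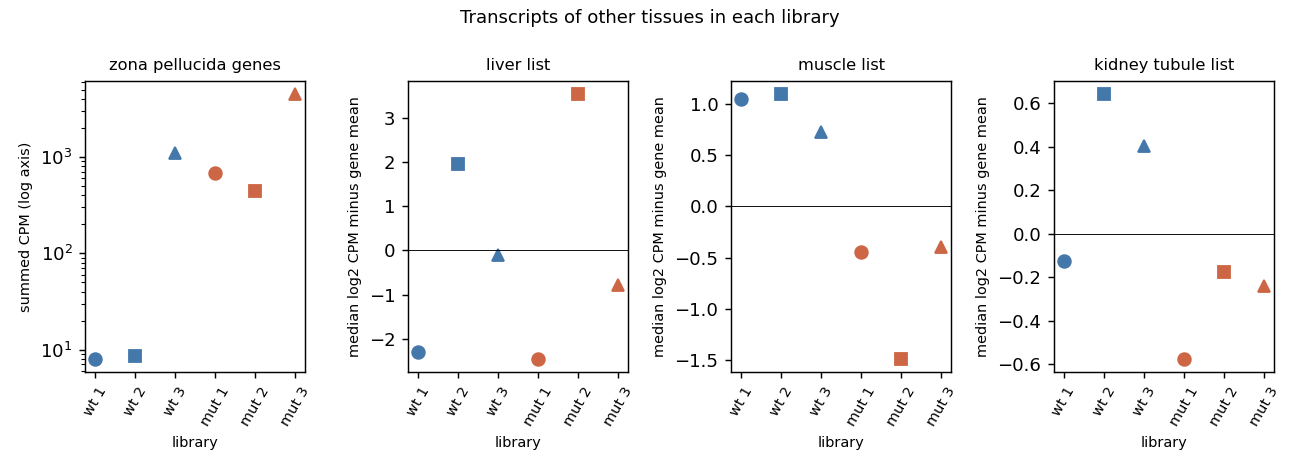
Transcripts of other tissues with 1 point per library, as summed zona pellucida CPM on a log axis and, for the liver, muscle and kidney tubule lists, as the median over members of log2 CPM minus the member's mean. Zona pellucida transcripts run from 8.004 CPM in wild type 1 to 4491 CPM in tet2 mutant 3, and the muscle medians lie below 0 in the 3 mutant libraries and above 0 in the 3 wild type libraries.

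Erythroid genes had 15 of 18 members below 0 (median -0.30) and fell as a list (camera of limma, Benjamini-Hochberg adjusted p = 0.0144), with adjusted p = 0.893 with an estimated correlation. The ammonium channel gene RHAG of red cells had 541 ± 48.8 CPM in wild type and 374 ± 41.3 in mutants, and alas2, which starts heme synthesis in these cells, 915 ± 116 and 687 ± 168. This call ended without wild type 2 (median -0.20), wild type 3 (-0.28) and tet2 mutant 3 (-0.10), and without both libraries numbered 3 (median -0.11; camera of limma, Benjamini-Hochberg adjusted p = 0.855). Haemoglobin genes took 2.57 ± 0.523% of counts in wild type and 2.22 ± 0.577% in mutants, a difference of -0.347 percentage points (exact permutation p = 0.5). This difference was -0.0139 without tet2 mutant 3, -0.126 without wild type 3 and -0.635 without wild type 1, and also moved to -0.510 without tet2 mutant 1 and -0.517 without tet2 mutant 2. Heme synthesis genes had 14 of 19 members below 0 (median -0.13; camera of limma, Benjamini-Hochberg adjusted p = 0.091), with the ferritin gene fth1a at 2373 ± 129 and 1769 ± 263 CPM. With the replicate block that list fell (adjusted p = 0.0339 by camera of limma with Benjamini-Hochberg adjustment), with adjusted p = 0.937 with an estimated correlation. Heme synthesis genes also passed without wild type 3 (median -0.21) and without tet2 mutant 1 (-0.25), though 0 lists passed there with an estimated correlation. With the egg covariate the erythroid median was -0.16 (camera of limma, Benjamini-Hochberg adjusted p = 0.116) and the heme synthesis median 0.04.

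Stem and progenitor genes had 12 of 17 members below 0 (median -0.05; camera of limma, Benjamini-Hochberg adjusted p = 0.0917). The transcription factor gene LMO2 had 75.4 ± 5.37 and 54.5 ± 7.48 CPM and the receptor gene KIT 21.3 ± 4.86 and 12 ± 3.19; with the replicate block KIT and MYB were lower when adjusted over the list alone, and with the egg covariate the log2 fold change of KIT was -0.40, against -0.83 without it. Thrombocyte genes had a median of -0.16 over 20 members (adjusted p = 0.0783 by camera of limma with Benjamini-Hochberg adjustment). Among them blf, a zinc finger gene, was lower when adjusted over the list alone (119 ± 5.11 and 72.2 ± 3.88 CPM) and over all genes with the replicate block (log2 fold change -0.72; edgeR, Benjamini-Hochberg adjusted p = 0.0456). THBS1, a platelet matrix gene, had 47.6 ± 10.6 and 28.4 ± 5.9 CPM. Stem and progenitor genes passed by camera without wild type 3 (median -0.22) and without tet2 mutant 1 (-0.25), and thrombocyte genes without tet2 mutant 1 (-0.24), while 0 lists passed in these fits with an estimated correlation. Neutrophil genes had a median of 0.02 over 13 members, with the protease gene MMP9 at 134.5 ± 57.2 and 252 ± 100 CPM and illr4 at 116 ± 11.8 and 135 ± 25.9. Macrophage genes had a median of 0.02 and a mean of -0.04 over 24 members. Their MFAP4 copy ENSDARG00000038683 (45.2 ± 6.45 and 18.0 ± 5.0 CPM) was lower when adjusted over the list alone and over all genes with the replicate block (log2 fold change -1.35; edgeR, Benjamini-Hochberg adjusted p = 0.0201). A further copy, ENSDARG00000038681, had 19.1 ± 3.25 and 6.93 ± 3.7 CPM and was lower with the replicate block when adjusted over the list alone (log2 fold change -1.47 without the block and -0.96 with the egg covariate), and both overlap other members of this gene cluster.

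Among lymphoid lists, B cell genes had a median of 0.03 over 19 members, with the receptor gene cd79b at 15.2 ± 0.403 and 23.7 ± 5.35 CPM and the transcription factor gene IRF4 at 17.4 ± 1.47 and 13.5 ± 0.973. T cell genes had 14 of 18 members below 0 (median -0.23; camera of limma, Benjamini-Hochberg adjusted p = 0.0534), with the costimulator gene cd28 at 9.63 ± 2.77 and 5.80 ± 0.965 CPM and RUNX3 at 53.4 ± 5.57 and 42.0 ± 4.25. This list passed by camera without wild type 1 (median -0.40), without tet2 mutant 1 (-0.34), with DESeq2 (-0.22), with no filter (-0.24) and with the egg covariate (-0.39), and in each of these fits 0 lists passed with an estimated correlation. NK-like genes had a median of 0.16 over 18 members, with the perforin gene prf1.3 at 1.08 ± 0.186 and 2.55 ± 0.512 CPM. EOMES (ENSDARG00000006640), a transcription factor gene of cytotoxic lymphocytes, had 10.9 ± 3.34 and 22.9 ± 7.81 CPM and was higher with the replicate block (log2 fold change 1.06; edgeR, Benjamini-Hochberg adjusted p = 0.0324). With the egg covariate the log2 fold change of EOMES was 0.48 (edgeR, Benjamini-Hochberg adjusted p = 0.566). EOMES and prf1.3 were also higher with the replicate block when adjusted over the list alone. For the neutrophil, macrophage, B cell and NK-like lists, camera of limma gave Benjamini-Hochberg adjusted p values between 0.259 and 0.9.

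Interferon response transcripts were higher as a list, with 23 of 24 members above 0 (median 0.48; camera of limma, Benjamini-Hochberg adjusted p = 8.57e-06, and adjusted p = 0.877 with an estimated correlation). The antiviral genes CMPK2 (2.82 ± 1.08 and 6.12 ± 0.429 CPM) and pkz (11.5 ± 3.15 and 19.97 ± 3.03) did not pass by edgeR or voom and were called by DESeq2 (Benjamini-Hochberg adjusted p = 0.0227 and 0.0391), and mxc (65.7 and 135 CPM) was higher with the replicate block when adjusted over the list alone. Cell cycle transcripts were also higher as a list, with 22 of 26 members above 0 (median 0.28; camera of limma, Benjamini-Hochberg adjusted p = 0.00083, and adjusted p = 0.877 with an estimated correlation). The ribonucleotide reductase gene RRM2 had 116 ± 27.6 and 210 ± 95.5 CPM, and the mitotic cyclin gene CCNB1, also abundant in eggs, 102 ± 36.2 and 212 ± 126. With the replicate block CCNB1 passed over all genes (log2 fold change 0.97; edgeR, Benjamini-Hochberg adjusted p = 0.0428), CCNB1 and MCM6 were higher when adjusted over the list alone, and with the egg covariate its log2 fold change was 0.20. Without wild type 1 the medians were 0.76 for the interferon response and 0.42 for the cell cycle, and the latter was 0.14 without wild type 3, all past the threshold by camera with the preset correlation. With the egg covariate the list medians were 0.91 for the interferon response and 0.35 for the cell cycle, and both lists passed with the preset correlation but not with an estimated one (adjusted p = 0.774 for each by camera of limma, Benjamini-Hochberg).

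Hox and Meis genes, which set positional identity and act in blood progenitors, fell as a list, with 19 of 24 members below 0 (median -0.52; camera of limma, Benjamini-Hochberg adjusted p = 0.00126, and adjusted p = 0.877 with an estimated correlation). When adjusted over the list alone, hoxa10b (1.44 ± 0.235 and 0.353 ± 0.0485 CPM) and MEIS2 were lower and meis3 (0.771 ± 0.0678 and 2.19 ± 0.588) was higher, and hoxa10b was lower over all genes with the replicate block (log2 fold change -2.01; edgeR, Benjamini-Hochberg adjusted p = 0.042). Kidney tubule, muscle, endothelial and stromal lists moved the same way. In the antigen presentation list the median was 0.01 and the mean -0.29 over 19 members (camera of limma, Benjamini-Hochberg adjusted p = 0.637); it passed without wild type 3 (median -0.13) and with the egg covariate (median 0.34), and in both fits 0 lists passed with an estimated correlation. There mhc1uba fell over all genes, and the class II gene mhc2dab was lower when adjusted over the list alone and, with the replicate block, over all genes (188 ± 126 and 6.31 ± 1.36 CPM, log2 fold change -4.61; edgeR, Benjamini-Hochberg adjusted p = 0.0282). The peptide loading gene tapbp.1 was higher with the replicate block when adjusted over the list alone.

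DNA methylation genes did not pass as a list, with a median of -0.06 and a mean of 0.06 over 19 members. The methyltransferase genes dnmt3bb.3 and DNMT1 had 13.1 ± 1.56 and 17.8 ± 4.62 CPM, and 175 ± 44.0 and 235 ± 52.8. Single-strand break repair genes had a median of 0.14 over 21 members, with the polymerase gene POLB at 14.3 ± 1.64 and 21.6 ± 5.2 CPM and tdp2a, which removes topoisomerase II remnants, at 1.05 ± 0.291 and 2.04 ± 0.589. Homologous recombination and Fanconi genes had 19 of 28 members above 0 (median 0.15), although RAD51B, a recombinase paralog, had 11.1 ± 2.06 and 4.67 ± 1.56 CPM (log2 fold change -1.24; called by DESeq2, Benjamini-Hochberg adjusted p = 0.00385, and by edgeR without both libraries numbered 3, at -1.69 and adjusted p = 0.0396) and BARD1 5.55 ± 0.659 and 7.88 ± 0.40. In the p53 response list (median -0.03, 19 members) tigara, a regulator of glycolysis, was higher and the cyclin gene CCNG2 lower when adjusted over the list alone, at 8.49 ± 0.605 and 15 ± 0.827 CPM and 57.2 ± 5.1 and 39.0 ± 4.51, and bbc3 was lower there with the replicate block. Single-strand break repair genes passed by camera without wild type 1 (median 0.18), as did homologous recombination and Fanconi genes (0.28), with 0 lists passing in that fit with an estimated correlation. The former also passed with the egg covariate (median 0.09; camera of limma, Benjamini-Hochberg adjusted p = 0.0372, and adjusted p = 0.774 with an estimated correlation). For these 4 lists with all 6 libraries, camera of limma gave Benjamini-Hochberg adjusted p values between 0.176 and 0.875.

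Stress and inflammation lists did not pass either. Inflammatory cytokine genes had a median of -0.06 over 24 members, with the nitric oxide synthase gene NOS2 at 2.51 ± 3.02 and 0.434 ± 0.158 CPM and il6 at 0.236 ± 0.032 and 0.46 ± 0.149. Immediate early genes had a median of -0.10 over 24 members, with ier2a at 37.1 ± 6.06 and 24.1 ± 3.37 CPM and the RNA decay gene ZFP36L1 at 72.1 ± 4.37 and 57.6 ± 4.87. Heat shock genes had a median of -0.04 over 22 members, while camera's direction was upward. The collagen chaperone gene SERPINH1 had 1.28 ± 0.744 and 0.415 ± 0.114 CPM and the secretory pathway chaperone gene HSPA5 251 ± 125 and 562 ± 286. The adjusted p values by camera of limma (Benjamini-Hochberg) lay between 0.257 and 0.968.

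**Figure D3:**
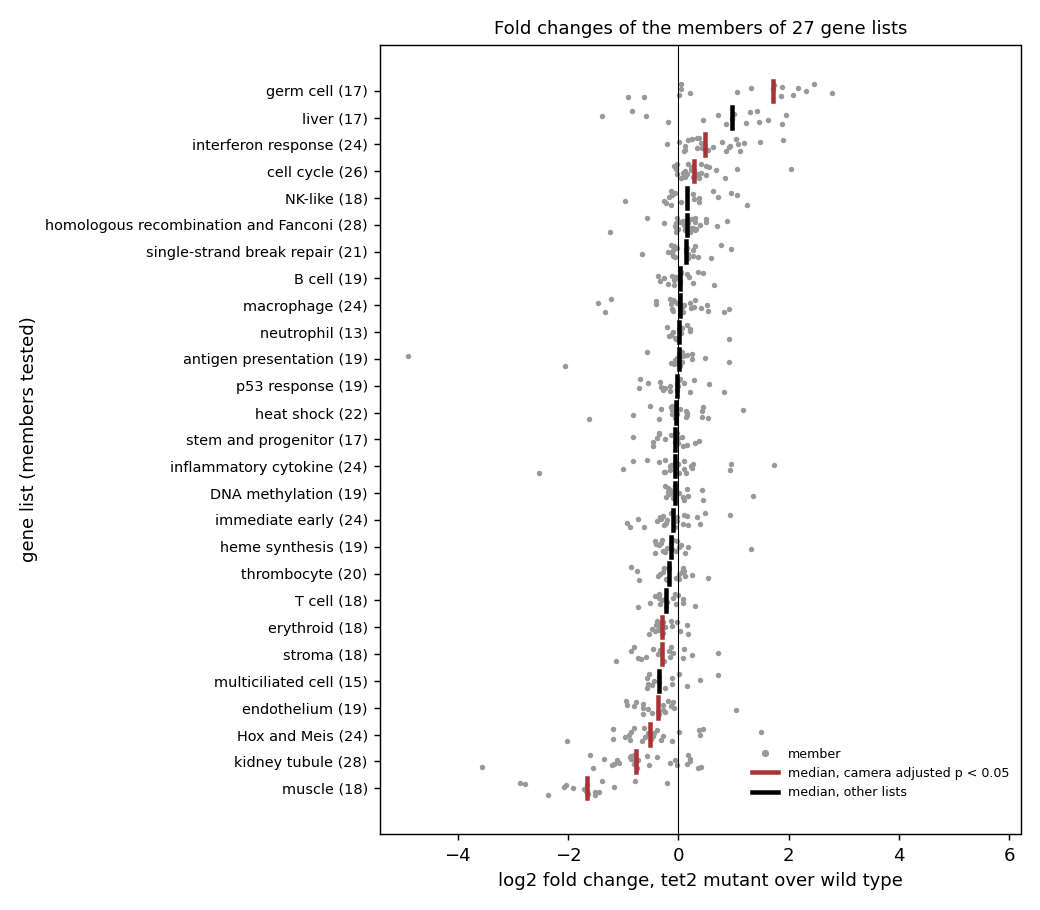
Log2 fold changes, tet2 mutant over wild type, of the measured members of 27 gene lists (grey points), with a bar at each median and the number of members in brackets. Bars in red mark the 9 lists past the threshold of camera with the preset correlation, 3 above 0 and 6 below.

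In all, 9 of the 27 lists passed camera with the preset correlation, and 0 passed with an estimated correlation or by fry's directional test, whose lowest Benjamini-Hochberg adjusted p values (limma) were 0.323 and 0.0521. In 25 lists 0 members passed over all genes by edgeR; among their 489 genes, 76 had an unadjusted p under 0.05, DESeq2 called 31 and voom 1. Over all genes tested, 2612 of 21893 had such an unadjusted p. By fry's mixed test, 7 lists changed in either direction, namely kidney tubule, muscle, macrophage, thrombocyte, p53 response, antigen presentation, and Hox and Meis. That test does not compare a list with other genes. In that order, 12 of 28, 14 of 18, 4 of 24, 2 of 20, 4 of 19, 3 of 19 and 6 of 24 members had an unadjusted p under 0.05. Under the replicate block 7 passed by this test, where stem and progenitor (limma, Benjamini-Hochberg adjusted p = 0.0439) and NK-like (0.0361) took the place of muscle and thrombocyte (0.0779 each). The number was 10 without wild type 1, 2 without wild type 2, 1 without wild type 3, 2 without tet2 mutant 2 and 0 with the egg covariate.

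The region around TET2 was compared with the rest of the genome, because a mutant line can carry another haplotype there. Within 10 Mb of TET2, 2 of 249 tested genes had changed, PRSS12 and the transcription factor gene GTF2F2 (72.2 ± 6.86 and 36.8 ± 0.77 CPM, chosen after its values were seen), against 64 of 21643 elsewhere. The odds ratio was 2.73 (95% interval 0.322 to 10.4, Fisher's exact p = 0.173). It was 0 with each library left out in turn, when 0 changed genes lay in the region by edgeR.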

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

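The egg covariate and the removal of both libraries numbered 3 were chosen only after the result was seen; all other alternatives were fixed in advance. Over all alternatives, named genes other than TET2 kept their direction and their side of the threshold 1141 times, lost a call 132 times, gained one 31 times and reversed 6 times. TET2 kept its direction without a call under all its alternatives (-0.39 to -0.06 with 1 library left out), as did the haemoglobin share under those run for it (-0.635 to -0.0139 with 1 library left out). Of the 66 changed genes, 61 remained with DESeq2 size factors, 66 with upper-quartile factors, 62 without haemoglobin genes, 60 with no filter, 55 with at least 1 CPM in 3 libraries, 65 with robust dispersion, 54 with voom and 31 with the egg covariate. Depth limits genes near 0.1 CPM, and in simulated counts 1 of 67 changes of 2-fold was called without the block.

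DESeq2 called 999 genes (404 higher, 595 lower, 763 at least 2-fold), and library totals alone gave 36 (12 higher, 24 lower, 36 at least 2-fold). With the replicate block 468 genes changed (257 higher, 211 lower, 438 at least 2-fold), the neutrophil median was -0.0090 and the liver median -0.075; it changed no other call of the named genes, lists and families beyond those given beside their results. Leaving out 1 library gave 2 to 15 changed genes (0 to 5 higher, 1 to 11 lower, 2 to 15 at least 2-fold), where fewer samples lower the power. Without both libraries numbered 3, 312 genes changed (249 higher, 311 at least 2-fold). With an estimated correlation 0 lists passed, here and under each alternative fit, and by fry's directional test 0, against 1 with upper-quartile factors and 1 without tet2 mutant 2. The odds ratio near TET2 was 0 in the 5 Mb window, with library totals alone and with any library left out, 0.771 with DESeq2 and 1.13 with the replicate block. Apart from fewer samples, the cause was not tested for these or the following values.

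The medians of 16 lists changed sign under some alternative, 3 times past the threshold (germ cell with the egg covariate, liver without tet2 mutant 2, antigen presentation without wild type 3). The macrophage median was -0.017 with DESeq2, -0.042 with upper-quartile factors and -0.035 with no filter; voom gave -0.0076 for neutrophils and -0.090 for liver. Upper-quartile factors, which move the median of all genes to -0.049, gave -0.036 for neutrophil, -0.042 for B cell and -0.041 for antigen presentation genes. Heat shock genes had 0.032 at 1 CPM in 3 libraries. With the egg covariate the medians were 0.0036 (thrombocyte), -0.63 (germ cell), 0.073 (DNA methylation), 0.11 (p53 response), 0.086 (inflammatory cytokine), 0.026 (heat shock) and 0.041 (heme synthesis), and the log2 fold changes 0.0096 (tet3) and -0.31 (tdrd5). Without both libraries numbered 3 they were 0.11 for tet3, 0.031 for DNA methylation and -0.010 for homologous recombination and Fanconi genes. With 1 library left out they ran from -0.21 to 0.19 (neutrophil), -0.14 to 0.030 (macrophage), -0.064 to 0.053 (B cell), -0.67 to 0.062 (multiciliated cell), -1.84 to 2.80 (liver), -0.14 to 0.053 (DNA methylation), -0.0029 to 0.23 (single-strand break repair), -0.00063 to 0.28 (homologous recombination and Fanconi), -0.10 to 0.10 (p53 response), -0.084 to 0.14 (inflammatory cytokine), -0.13 to 0.16 (antigen presentation), -0.19 to 0.024 (immediate early), -0.071 to 0.027 (the list heat shock), -0.21 to 0.081 (tet3), -1.28 to 2.71 (fabp10a) and -1.42 to 3.15 (tfa).

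Outside the leave-one-out fits, cplx2a lost its call with DESeq2 size factors, library totals alone, haemoglobin genes removed, at least 1 CPM in 3 libraries and the egg covariate, and otoa with voom, library totals alone and without both libraries numbered 3. Library totals alone also ended the calls of dtx3lb.3, fbxo44.9, PRSS12, SLC5A12 and cltrn. The egg covariate ended those of areg, dtx3lb.3, fbxo44.9, linc-iglc3, mhc1uba, SLC5A12 and cltrn, with the same direction and adjusted p between 0.0633 and 0.144 (edgeR, Benjamini-Hochberg). DESeq2 called a further 18 named genes, namely both MFAP4 and both POSTN copies, prf1.3, EOMES, blf, clec14a, ESAM, TNNI2, tpma, RAD51B, tigara, CCNG2, CMPK2, pkz, hoxa10b and meis3; voom, upper-quartile factors and robust dispersion each added TNNI2. The heme synthesis list passed with library totals alone.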

Other observations

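In this part the correlation of egg transcripts, the tests of the genes higher with the block in separate parts, the count of changed genes on other chromosomes than TET2, the gene families, the count of changed genes lying close together and the genes named in its first 2 paragraphs were chosen only after the result was seen. The kidney segment sets, the muscle genes outside the list and the other egg genes were also written down after the main fit was seen. Class II histocompatibility genes on chromosome 8 differed in level while a neighbour did not pass. The beta chain gene mhc2dab, whose product presents antigen, had 308, 199 and 55.6 CPM in wild type 1, 2 and 3 and 4.80, 7.45 and 6.68 CPM in the mutant libraries, a log2 fold change of -4.89 (SE 0.65; edgeR, Benjamini-Hochberg adjusted p = 0.0539) and of -4.61 with the replicate block (adjusted p = 0.0282, edgeR with Benjamini-Hochberg). Its neighbour mhc2daa had 454 ± 132 CPM in wild type and 377 ± 30.6 in mutants (n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.69). All 5 class II genes tested were below 0 under each scaling. Without the block 0 passed by edgeR with 3 at an unadjusted p under 0.05, 3 passed by DESeq2, 0 by voom and 1 with upper-quartile factors; with the replicate block 3 passed (mhc2dab, mhc2bl and mhc2d8.37a2). Class I genes did not move together, with 10 of 16 below 0 and 6 above (median -0.17). Among them only mhc1uba passed, with the replicate block as without it. In the mfap4 family, a cluster on chromosome 1 with macrophage members, 10 of 13 genes were below 0 under each scaling (median -0.80). Of these 0 passed by edgeR with 8 at an unadjusted p under 0.05, 5 passed by DESeq2 and 0 by voom, and 4 were lower with the replicate block, mfap4.6 among them (185 ± 21.5 and 83.6 ± 25.7 CPM).

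The fall of taco1, whose product activates translation of the mitochondrial COX1 message, stood beside values of that message. MT-CO1 had 18542 ± 1513 CPM in wild type and 12065 ± 1773 in mutants (n = 3), a log2 fold change of -0.63 with the replicate block (edgeR, Benjamini-Hochberg adjusted p = 0.0173) and -0.62 without it (adjusted p = 0.15, edgeR with Benjamini-Hochberg). MT-ND2, a respiratory complex I gene, had 611 ± 160 and 1186 ± 220 CPM and was higher with the block (log2 fold change 0.97; edgeR, Benjamini-Hochberg adjusted p = 0.0394; 0.163 without it). Of 13 mitochondrial messages 9 were below 0, and 10 with upper-quartile factors. Muscle genes outside the fixed list were among the changed genes, with the protease gene CAPN3 (ENSDARG00000041864) falling from 2.32 ± 0.478 to 0.145 ± 0.0625 CPM, spega from 2.01 ± 0.467 to 0.221 ± 0.0133, and LMOD2 (ENSDARG00000045634) from 0.827 ± 0.144 to 0.0345 ± 0.0118. The symbols CAPN3 and LMOD2 each stand on 2 gene IDs. TMEM179 overlaps CAPN3 on the same strand, so its reads are of uncertain origin. CAPN3 also starts at 45191718 on chromosome 17, beside the changed gene GANC, which ends at 45189197. In the ftr family of TRIM genes 1 of 65 passed, ftr80, which was higher in mutants (443 against 3 counts, a ratio of 134 with a 95% counting interval of 45.5 to 651), while DESeq2 called 16. In this family 5 genes passed with the replicate block, 3 higher and 2 lower (ftr88 and ftr96). All 21 zona pellucida genes were above 0 under each scaling; 0 passed by edgeR with 1 at an unadjusted p under 0.05, DESeq2 called 1 and voom 0, and 5 were higher with the replicate block.

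Near silence in 1 genotype, with a mean under 0.1 CPM, marked 23 of the 66 changed genes. Different haplotypes around the changed genes in the mutant and wild type lines are a candidate explanation, since 211 of 1216 unchanged genes within 500 kb of a changed gene had an unadjusted p under 0.05 (17.4%), against 2335 of 20611 farther away (11.3%; odds ratio 1.64, 95% interval 1.40 to 1.92, Fisher's exact p = 1.89e-09, over genes that are not independent). Of the changed genes, 14 had another within 500 kb, against a median of 4 in 10000 random draws, of which 17 gave as many. Both tests used all 66 changed genes, so near silence itself was not tested. Neither parts haplotypes from reads shared by near-identical copies that lie close together, whose origin is uncertain here. A haplotype linked to TET2 cannot itself hold most of the changed genes. Of the 66, 60 (90.9%, exact 95% interval 81.3 to 96.6) were not placed on its chromosome, and 0 lay within 5 Mb. The 60 include 1 gene each on the scaffolds KN150630.1, KN150637.1 and KN150683.1, whose chromosome is not given. For the genes within 10 Mb a linked haplotype and its absence cannot be told apart (odds ratio 2.73, interval 0.322 to 10.4). The genotype itself stays open, and the 10 splits of 6 libraries are too few for a share under 0.05, with 66 changed genes in the real split, the 1 split to reach that number, and 0 in the highest of the others (468 and 0 with the replicate block among the 4 splits that part all 3 pairs, while the other 6 part 1 pair). At an unadjusted p under 0.05 the real split had 2612 genes, while the others had from 204 to 2915.

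Kidney tubule and muscle transcripts were lower as lists by camera with the preset correlation but not with an estimated one (adjusted p = 0.877 and 0.323, limma with Benjamini-Hochberg), with member medians of -0.12, 0.64 and 0.40 in wild type against -0.58, -0.18 and -0.24 in mutants for the kidney, and of 1.05, 1.09 and 0.72 against -0.44, -1.49 and -0.40 for muscle. Less skeletal muscle in the mutant suspensions is consistent with 57 muscle genes outside the list, whose median was -1.01, with 52 below 0 (91.2%; 51 with voom) and summed levels of 841, 884 and 891 CPM in wild type against 665, 669 and 715 CPM in mutants. These muscle sums fell by a smaller factor than the median of the same genes. The genes thus did not share 1 factor of change, which limits that reading. For the kidney, 14 proximal genes had a median of -0.71 and 8 distal tubule and glomerulus genes one of -0.64, a difference of -0.077 (bootstrap interval -1.06 to 0.85, permutation p = 0.833 over genes). That interval is too wide to part less kidney tissue from a change within tubule cells, so these cannot be told apart. Summed levels overlapped between the genotypes for proximal, distal and glomerulus genes alike. Proximal genes summed to 865, 971 and 754 CPM in wild type against 755, 818 and 668 CPM in mutants. No member of either list stands in another list, and the genotype stays open as an untested cause of either difference.

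Egg transcripts differed between libraries, with zona pellucida CPM of 8.004, 8.62 and 1105 in wild type and 679, 442 and 4491 in mutants, and 6 other egg genes at 7.69, 6.97 and 278, and 115, 72.5 and 697 CPM. The sets rose and fell together over the 6 libraries (Spearman's rho 0.943, exact permutation p = 0.0167; Pearson's r of log2 values 0.989, exact permutation p = 0.00278), which is consistent with egg material in some suspensions; wild type 1 and 2 lie apart from the others, and over the other 4 libraries, too few to test, r was 0.976. With the replicate block 257 genes were higher. Of these 106 (41.2%) were at least 4-fold higher in wild type 3 than in wild type 1 and 2. The share was 1.68% among the other genes (Fisher's exact p = 7.01e-110, over genes that are not independent and rest on 1 library). Among the 21 also called without the block it was 0 genes, and among the other 236 it was 106 (44.9%). The 21 kept a median of 99.7% of their log2 fold change with the egg covariate (77.1 to 128%), all over 2 SE above 0. Of them 6 still passed, as the median SE rose from 0.38 to 0.50. Picked by the test without the block, these 21 genes lacked overlap between genotypes. Wild type 3 had more zona pellucida CPM than tet2 mutant 1 and 2, so a gene that followed egg content could hardly be among them. Egg content alone would place wild type 3 (1105 CPM) above tet2 mutant 1 and 2 (679 and 442 CPM). All 21 genes were instead lower in wild type 3 than in these mutant libraries. Egg content alone thus did not order them, a point that rests on wild type 3. The share kept and the 0 of 21 cannot decide whether egg material played a lesser part. The other 236 kept a median of 30.5% of theirs with that covariate (-94.8 to 182%), with 106 over 2 SE above 0 and 10 passing. For these 236, egg material and genotype cannot be told apart, since the mutant had more egg transcripts than the wild type of the same number in all 3 pairs. The genotype stays open for all 257 genes. Some of the 236 may be false calls, since 15.4% of calls with the block were false in simulated counts.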
